A study of Picea abies with 24 samples.

How the data were processed

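RNA was compared between 6 embryogenic cultures of Norway spruce (Picea abies) on 24 two-colour cDNA microarrays. Per the labels, 3 lines carried the asCCR construct (A78:3, A78:4 and A78:5), 2 were transformed control lines (G88:5 and G88:9) and 1 was untransformed. The untransformed line is written 95:88:22 in the sample titles, and that name is used here, although the series description writes a different middle part. Each line gave 2 biological replicates, each taken from 3 Petri dishes on day 14 after subculture, so 12 RNA extracts were hybridised. The arrays of each replicate formed a closed loop of 12 arrays in which asCCR lines alternated with control lines and each pairing was repeated with the dyes exchanged. No array joined the 2 loops.

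Per the file headers, the deposited scanner files held spot intensity values in the Cy5 and Cy3 channels from QuantArray, without background subtraction. Per the labels, the authors normalized the arrays by print-tip loess within each slide in the LCB Data Warehouse version 1.2.10 and tested genes with a mixed model. Which effects that model took as random is not given in the sources used here. The deposited series matrix held log2 ratios. For 23 arrays these were log2 Cy5 over Cy3 after print-tip loess without background subtraction: values recomputed that way from each array's own scanner file differed by at most 0.00337, which settled scale and direction. The column medians lay between -0.00358 and 0.0193. For the array with A78:4 in Cy5 and G88:5 in Cy3 of replicate 1, the scanner file was identical to that of the array with A78:5 in Cy5 and 95:88:22 in Cy3 of replicate 1. It matched the log2 ratios of the latter and had an r of -0.0127 with those of the former. The former was left out, and 23 arrays were fitted. The series matrix column of that array, which had no scanner file of its own to set it against, entered only as an alternative.

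Intensities were corrected with normexp (offset 50) and normalized by print-tip loess (span 0.3) over the 48 print blocks in limma 3.58.1 under R 4.3.3. Spots marked as ignored in the files were left out, 170 over all arrays. Adjacent print blocks held the same features in the same order. The mean log2 intensity of the paired spots had an r of 0.987 over 2688 pairs, against -0.0255 to 0.352 for neighbouring blocks that were no pair. The 2 spots were averaged, which gave 2688 features. A feature was to be kept if its spot lay 2 background SDs above background in either channel on at least 12 arrays. All 2688 passed, also with all arrays required, because the recorded background was near 0 on most arrays. This filter therefore tested nothing.

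Least squares in each loop gave 1 level per extract, centred over the 6 lines, and 1 dye term per feature, which averaged the dye swaps. The asCCR class was compared with the control class on the 6 line means with limma, with the line as the independent unit (3 against 3). Single lines were compared on the 12 extract levels with line and replicate number in the model, so that the spread between the 2 extracts of a line was the error, with 5 residual degrees of freedom. The replicate number was part of the design because each replicate had its own loop. In single-channel values the replicate differences of the lines had r between -0.637 and 0.733 over 15 pairs of lines, with a median of 0.0737. Lines on the same array share its slide in these values. They therefore do not settle whether the numbers otherwise paired the extracts. P-values were adjusted by Benjamini-Hochberg and called under 0.05. The number of arrays limits the precision.

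The procedure was tested on simulated arrays with the measured spread and 200 changed features. The simulated lines of a class differed only by the spread between extracts, and noise was drawn independently for each feature. In the class comparison, 82.1% of features changed by 0.5 on the log2 scale and 100% of those changed by 1 or 2 were recovered among 2688 features. In the comparison of A78:3 with the control lines, the shares were 43.3% at 0.5, 97.0% at 1 and 100% at 2, and 5 of 2488 unchanged features were called.

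The files used here do not pair features with gene names or sequences. Features are written F with the numbers of their 2 spots. The rule for named features, set before the data were examined, took the largest changes among called features, or otherwise those with the smallest p as values only. It was limited to 2 features in each direction because no gene names were at hand. The check of the CCR probes and the tests of 19 gene lists are not analysed here for the same reason. The alternatives set before the data were examined covered background correction, normalization, scaling, the series matrix values, the filters, slide lot, the error term, the control lines, the replicate block and leaving out extracts, lines or loops. Alternatives chosen after seeing the data left out each pair of dye-swapped arrays, 3 arrays with low agreement of duplicate spots or dim features, removed array-specific dye patterns, used single spots or single-channel values with the replicate block, or took each group of slide lots alone.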

Results

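Transcript levels were measured in embryogenic cultures of Norway spruce in which, by the title of the series, a gene encoding CCR had been down-regulated. CCR, cinnamoyl-CoA reductase, catalyses the entry step of the branch of phenylpropanoid metabolism that makes the monolignols of lignin. The cultures were 3 asCCR lines, 2 transformed control lines without that construct and 1 untransformed line, with 2 RNA extracts per line. Each array carried 1 asCCR extract and 1 control extract. Values for 2688 features from 23 arrays entered the fits. The median intensity of an array lay between 556.9 and 6864 in Cy5 and between 675.8 and 4616 in Cy3, and the median background was 0 to 234.9. Normalized log2 ratios of the duplicate spots on an array had a Pearson r between 0.182 and 0.802 across features, which are not independent replicates. The level of CCR itself, which would check the labels, was not analysed here, since the files used here do not pair features with genes.

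**Figure D1:**
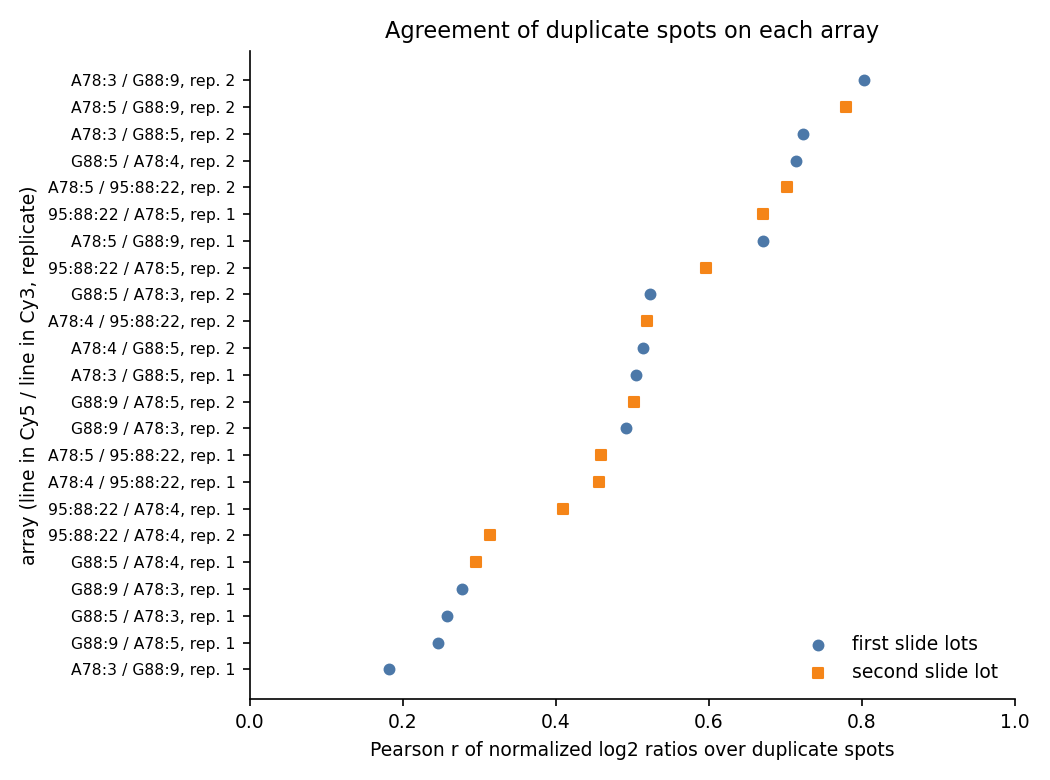
Pearson r of the normalized log2 ratios over the duplicate spots of 2688 features on each of the 23 arrays (horizontal axis, no unit), with the line in Cy5, the line in Cy3 and the replicate named on the vertical axis and slide lots by colour and shape. The values run from 0.182, for A78:3 in Cy5 and G88:9 in Cy3 of replicate 1, to 0.802 for the same pairing of replicate 2.

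The first question was whether the 3 asCCR lines as a class differed from the 3 control lines. No feature of 2688 was called by limma. At an unadjusted limma p under 0.05 there were 44 (9 to 85 with single extracts left out), where evenly spread p-values would give 134.4. The count was 143 with the transformed control lines only and 1 in single-channel values without the replicate block. The differences between the class means were small. They had an SD of 0.10 on the log2 scale over features and ran from -0.64 to 0.43, and 1 feature exceeded 0.5 in size. The median half-width of the 95% confidence interval was 0.23, and for 2680 features, or 99.7%, the interval lay wholly within a 2-fold change in either direction. These intervals are not adjusted for the number of features. In 116 features, or 4.32%, all 3 asCCR line means lay on one side of all 3 control line means, where exchangeable lines would give 10%. Each array set an asCCR extract against a control extract. The class difference was thus measured directly, and differences within a class, its error, only indirectly. The lines were therefore not exchangeable, and values below 134.4 or 10% do not show that the classes were more alike than chance. The difference between the classes had an r of 0.231 across features between the 2 replicate loops.

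The features with the smallest p in each direction are given as values, since none passed. F1346_1458 had a mean level of -0.20 ± 0.09 (SD, n = 3 lines) in the asCCR lines and 0.20 ± 0.15 in the control lines, a difference of -0.40 (SE 0.10, limma adjusted p = 1.0), with 0 of 6 asCCR extracts and 4 of 6 control extracts above the loop mean. F1621_1733 had -0.19 ± 0.12 and 0.19 ± 0.20, a difference of -0.39 (SE 0.12), with 0 of 6 asCCR extracts and 5 of 6 control extracts above the loop mean. Its asCCR mean included 1 extract, A78:3 of replicate 2, that lay apart at -0.58. In the other direction, F3682_3794 had 0.15 ± 0.04 in the asCCR lines and -0.15 ± 0.15 in the control lines, with 4 of 6 asCCR extracts and 1 of 6 control extracts above the loop mean. F4742_4854 had 0.18 ± 0.15 and -0.18 ± 0.19, with 3 of 6 asCCR extracts and 1 of 6 control extracts above the loop mean. Both had a limma adjusted p of 1.0. The difference in F4742_4854, 0.36 with all extracts, was 0.17 without A78:5 of replicate 1, and without background correction it was 0.21, against 0.18 in place of 0.30 for F3682_3794. The differences of the 4 features, in the order given, were -0.52, -0.55, 0.38 and 0.62 on the first slide lots alone and -0.23, -0.18, 0.16 and 0.09 on the second. When the arrays were taken as independent, against the design, 8 features were called, 2 higher and 6 lower in the asCCR lines, and F1346_1458 and F1621_1733 were among those lower.

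The slides were put here in 2 groups of lots. The lots follow the ranges of the number that ends each sample title, and the titles name no lot. The first lots join several such ranges, among them a range that held arrays of G88:9 of replicate 1 only. The pairings of A78:4 with G88:5 and of A78:5 with G88:9 were on the first lots in 1 replicate and on the second lot in the other, and each remaining pairing was on 1 group only, with A78:3 hybridised only on the first lots and 95:88:22 only on the second. With a dye term for each group of lots, 0 features were called in the class comparison and 40 had an unadjusted p under 0.05 in limma. Over the 6 dye-swap pairs on the first lots alone, 0 were called and 218 had an unadjusted p under 0.05, and over the 5 pairs on the second lot the numbers were 0 and 86. Pairs within a lot share extracts, so these last counts overstate the evidence. The mean asCCR over control ratio had an r of 0.131 across features between the 2 groups of lots.

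Each asCCR line was then compared with the 3 control lines against the spread between duplicate extracts. A78:3 stood apart from the other asCCR lines in the number of small p-values, but no feature was called in it by limma with all 23 arrays. It was also hybridised only on the first slide lots, where the median SD of log2 ratios was 0.39, against 0.29 on the second. Its levels had the widest SD, 0.263 in replicate 1 and 0.248 in replicate 2, while the error was pooled over all lines. Line and slide lot thus cannot be told apart in the counts for A78:3. In A78:3, 331 features, or 12.3%, had an unadjusted p under 0.05. This count moved with single extracts, to 153 without 95:88:22, 160 without A78:4, 161 without G88:5 and 799 without G88:9, each of replicate 1, and to 214 without 95:88:22 of replicate 2. The smallest adjusted p was 0.0745, and 86 features differed from the control lines by more than 0.5 on the log2 scale, over a range of -1.29 to 1.01. In A78:4, 0 were called, 22 had an unadjusted p under 0.05 (5 to 89 with single extracts left out) and 2 features exceeded 0.5. In A78:5, 0 were called, 83 had an unadjusted p under 0.05 (33 to 224 with single extracts left out) and 11 exceeded 0.5. The 95% confidence interval, with a median half-width of 0.32 in each of these comparisons, lay within a 2-fold change for 98.0% of features in A78:3 and for 99.1% in each of the other 2 lines.

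**Figure D2:**
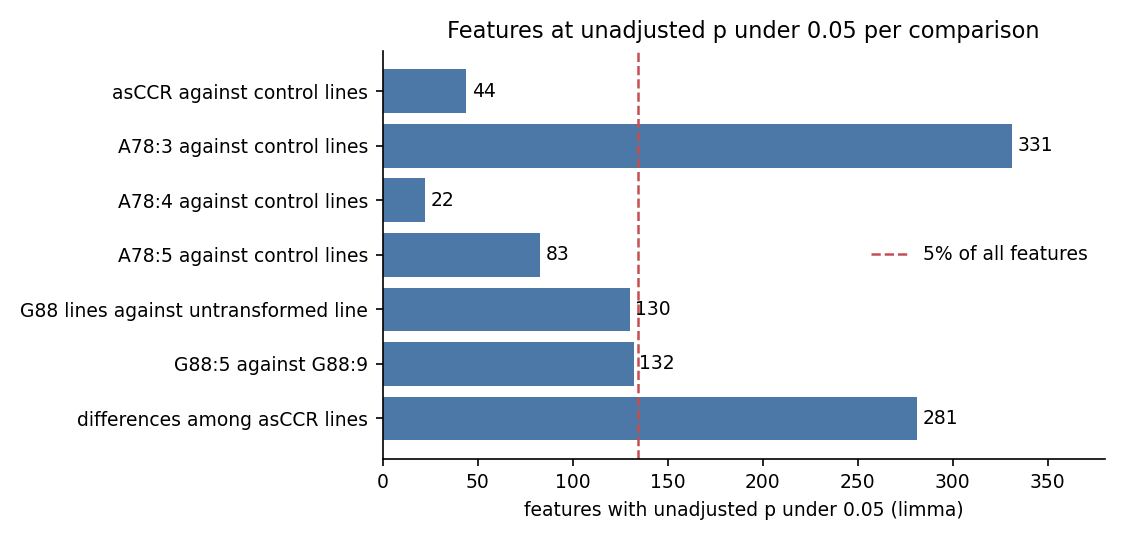
Number of features of 2688 with an unadjusted p under 0.05 in limma (horizontal axis, from 0) for each of the 7 comparisons, with the dashed line at the 134.4 features that evenly spread p-values would give. A78:3 against the control lines (331) and the differences among asCCR lines (281) lie above the line, and asCCR against control lines (44) lies below it.

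The number of features called in A78:3 changed with the arrays and values used. Without G88:9 of replicate 1, whose 4 arrays then left the fit, 248 features were called in A78:3 by limma, 105 higher and 143 lower than in the control lines. Their median difference was 0.52 in size on the log2 scale, over a range of -1.49 to 0.90, and 10 of them differed by 2-fold or more. With all arrays, all 248 had the same sign, a median size of 0.38, and 142 had an unadjusted p under 0.05. The series matrix values, which also hold the array without its own scanner file, called 11 features in A78:3, 7 higher and 4 lower, and all 11 were among the 248. With 2 dye patterns removed and every extract kept, 43 were called, 18 higher and 25 lower. Leaving out any other single extract called 0 features in A78:3.

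In the direct comparison of A78:3 with G88:5, the dye-swap mean ratios of replicates 1 and 2 had a Pearson r of 0.592 and a Spearman rho of 0.523 across the 2688 features. In both replicates, 11 features were more than 0.5 higher and 52 more than 0.5 lower in A78:3 on the log2 scale, and 1 exceeded 0.5 in opposite directions. Of the 248 features above, 241 had the direction of the call in both replicates of this comparison, whose arrays were also part of that fit. For A78:3 over G88:9 the r between replicates was -0.217, with 64 features beyond 0.5 in opposite directions, 6 higher in both replicates and 21 lower in both. The values were 0.365 for A78:4 over 95:88:22, 0.259 for A78:5 over G88:9 and -0.0555 for A78:5 over 95:88:22. For A78:4 over G88:5 the r in the series matrix values was -0.121.

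**Figure D3:**
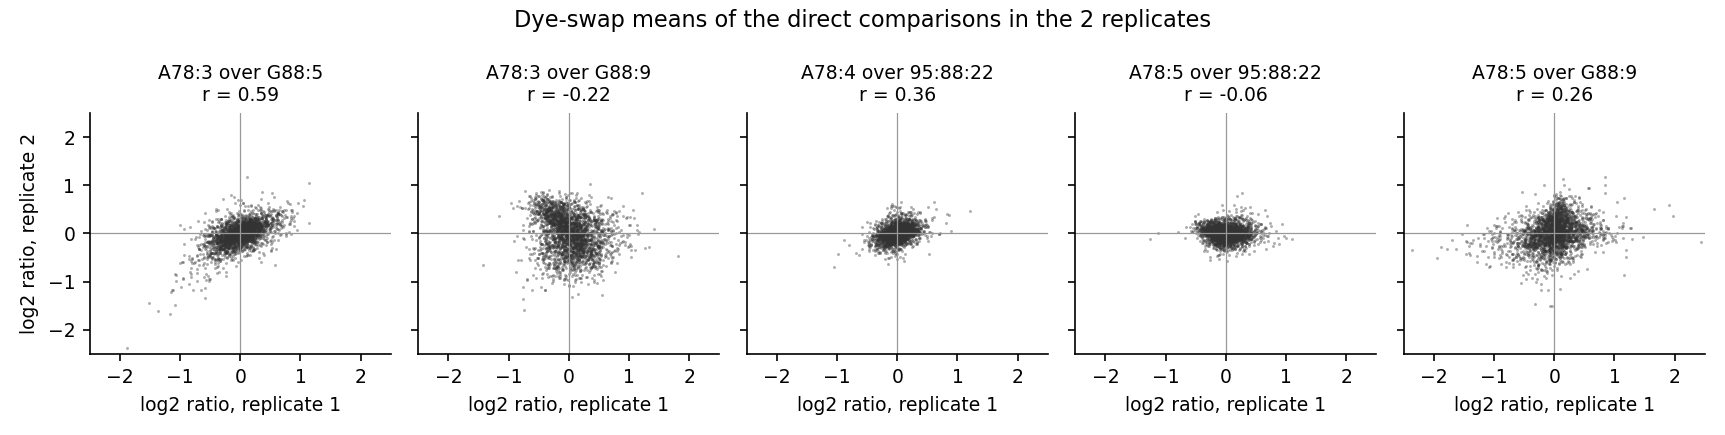
Dye-swap mean log2 ratios of 2688 features in replicate 1 (horizontal axis) against replicate 2 (vertical axis) for the 5 direct comparisons with both replicates, 1 point per feature. A78:3 over G88:5 has an r of 0.592, and A78:3 over G88:9 an r of -0.217.

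Whether the asCCR lines differed from one another was tested directly. With all arrays 0 features were called by the limma F test over A78:3, A78:4 and A78:5, and 281 had an unadjusted p under 0.05, or 115 without A78:4 of replicate 1 and 728 without G88:9 of replicate 1. A78:3 against A78:5 came closest in single pairs, with a smallest adjusted p of 0.0507 and 401 features at an unadjusted p under 0.05, against 225 for A78:3 and A78:4 and 52 for A78:4 and A78:5. Without G88:9 of replicate 1, 240 features differed among the 3 lines, and 162 of them were among the 248 called in A78:3.

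No feature was called in the same direction in all 3 asCCR lines, and 0 had an unadjusted p under 0.05 in the same direction in all 3. The log2 differences from the control lines had an r across features of 0.205 between A78:3 and A78:4, where unchanged lines against the same controls gave a mean of 0.0329 in 100 simulations. Their covariance was 0.00568 against a simulated 0.000931. Between A78:4 and A78:5 the r was 0.322 against 0.12, with a covariance of 0.00632 against 0.00341. Between A78:3 and A78:5 the r was -0.220 against 0.066, with a covariance of -0.00715 against 0.00177. The simulated noise was drawn independently for each feature. Real extracts of different lines in different loops had r between -0.602 and 0.461. The simulated values are therefore no chance reference for the r and covariances of the lines. When the controls were split by replicate, so that 1 line was taken from each loop, the r was -0.103 and 0.529 for A78:3 and A78:4, -0.346 and 0.271 for A78:3 and A78:5, and -0.128 and 0.0834 for A78:4 and A78:5. For each pair of lines the sign thus depended on which loop gave which line.

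The control lines were compared among themselves for differences without the asCCR construct. No array joined control lines, so these differences were reached only through asCCR extracts. The median SE was 0.152 for the G88 lines against the untransformed line and 0.176 for G88:5 against G88:9. It was 0.143 for each single asCCR line and 0.101 for the class. The sizes and counts below are therefore no like measure for those comparisons. No feature was called by limma between the 2 G88 lines together and the untransformed line. At an unadjusted p under 0.05 there were 130, where evenly spread p-values would give 134.4. That count was 7 without 95:88:22 of replicate 1, 64 without G88:5 of replicate 1, 213 without G88:5 of replicate 2 and 277 without G88:9 of replicate 1. The differences had an SD of 0.20 on the log2 scale, and 49 features exceeded 0.5. Between G88:5 and G88:9, 0 features were called, 132 had an unadjusted p under 0.05 (64 without 95:88:22, 71 without A78:4, 86 without G88:5, 456 without G88:9 and 754 without A78:3, each of replicate 1), the smallest adjusted p was 0.0645 and 73 features exceeded 0.5. Scaling between arrays, and separately the removal of 2 dye patterns, brought 1 feature past the threshold between G88:5 and G88:9. In single-channel values without the replicate block, 450 features were called between the G88 lines and the untransformed line, 234 higher and 216 lower in the G88 lines, and with the replicate block in the same values 302 were called. The untransformed line was only on the second lot and the G88 lines mostly on the first lots, and single-channel values do not cancel differences between slides as ratios do, so slide lot and line were confounded in these counts.

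Replicate extracts of a line resembled each other little. The levels of the 2 extracts had an r across features of 0.0347 for A78:3, -0.0872 for A78:4, 0.0903 for A78:5, -0.221 for G88:5, 0.176 for G88:9 and -0.0368 for 95:88:22, with a mean of -0.00723. Extracts of different lines in different loops had r between -0.602 and 0.461 over 30 pairs. The spread expected from array noise alone made up 45.7% of the variance of the levels in A78:3 of replicate 1 and 21.6% in replicate 2. In A78:4 it was 122% and 116%, and in the 8 extracts of the other lines it lay from 27.2% to 83.0%.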

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

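The tests of the patterns weighed here were chosen after the results were seen, except the test of dye bias in the A78:3 over G88:5 ratios, which was set before its result. For the test of the extract of G88:9 the bounds were set before its values were seen, but after related values, and the allowance for the spread was added after them. Of 10 groups of 6 extracts examined for an outlying extract, 2 had one, where chance gives about 1 in 20 groups. The level of F1621_1733 in A78:3 of replicate 2 was -0.58, while the other 5 asCCR extracts lay between -0.23 and -0.04. The SD of all levels in the extract of 95:88:22 of replicate 2 was 0.13, below the 0.19 to 0.22 of the other 5 control extracts.

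Extracts of the same line did not correlate between the replicate loops, with a mean r of -0.00723. In the deposited log ratios, 3 arrays had duplicate spots that correlated under 0.3 (5 in the background-corrected ratios, without which loop 1 could not be fitted), and without the 3 the mean r was 0.232, a value reached by 3 of 100 sets of 3 arrays of that loop, the real set included, with 0.266 the highest. All 3 were among the 4 arrays of G88:9 of replicate 1, and leaving out the other 3 sets of 3 of these 4 gave a mean r from 0.0889 to 0.23. The lowest was under the bound of 0.1 set against the extract, but by less than the SD of 0.0707 over the sets, the allowance added later. Each of these other sets also left out 2 of the 3 arrays of low duplicate-spot agreement. The test therefore cannot tell the extract apart from low array quality, with or without that allowance. Leaving out only the A78:3 and G88:9 arrays of replicate 1 gave a mean r of 0.225. Both are arrays of that extract with low duplicate-spot agreement, so this value does not separate the 2 explanations. Removing the 2 main patterns of the dye-swap sums, which held 46.9% and 14.8% of their variance, gave a mean r of 0.127. The SD of r over lines was 0.14 with all arrays. The highest of 100 removals of shuffled patterns gave -0.00614. Even that was near the -0.00723 without removal, so shuffled patterns are no reference for removing a main pattern. Dye bias of unequal size between arrays thus stays open. Array noise also lowers such r. It made up from 21.6% of the variance of the levels in A78:3 of replicate 2 to 122% in A78:4 of replicate 1. Differences between the cultures from which the replicates were taken remain open and untested.

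The ratios of A78:3 over G88:5 correlated between replicates with an r of 0.592. Dye bias along the 2 main patterns of the dye-swap sums was argued against, since the r was 0.581 once they were removed. These patterns held 46.9% and 14.8% of the variance of the sums, and dye bias outside them was not tested. Structured noise common to unrelated slide pairs stays open: 0 of 30 pairs of comparisons with no line in common reached that size, and the highest was 0.478, but 0.592 was singled out as the highest of 5 replicate correlations, and by chance alone the highest of all 35 would be one of these 5 in 14.3% of cases. Both replicates of this comparison were on the first slide lots, and an effect of these lots on the pairing of A78:3 and G88:5 was not tested. A difference between these 2 lines that belongs to the lines rather than to the construct is also open, because each is a separate transformant, so a biological difference remains a hypothesis.

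For the class comparison, all 10 splits of the 6 lines into 3 and 3 called as many features as the real one, which called 0, and the highest other split also called 0. Since the real split called 0, no split could call fewer, so this count tested nothing. With 10 splits no share under 0.05 can be reached either. At an unadjusted p under 0.05 the real split had 44 features and the other 9 splits had 29 to 592. Only the real split set its groups against each other on every array. The splits thus differed in precision, and these counts are no chance reference for the 44.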

How the results depend on the processing

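The class comparison called 0 features under 53 of 54 alternatives and 8 with the arrays taken as independent. A78:4, A78:5 and the shared calls stayed at 0 under all 40 alternatives run for each. Leaving out extracts or dye-swap pairs in turn gave 0 to 248 calls in A78:3 and 0 to 240 among the asCCR lines. The highest values came without G88:9 of replicate 1. Such fits assume that the lone extract left of a line varies like the other lines. Without the A78:3 and G88:9 pair of replicate 1 they were 137 and 15, without the A78:5 and G88:9 pair of replicate 1 they were 2 and 17, and without the A78:3 and G88:9 pair of replicate 2 A78:3 had 3. The 11 pairs were left out after seeing the data, as were the next 3 settings. Without the 3 arrays of low duplicate-spot agreement the counts were 110 in A78:3 and 9 among the asCCR lines. With 2 dye patterns removed they were 43 and 17, with 1 between G88:5 and G88:9. With both changes they were 67 and 8. The series matrix values gave 11 in A78:3, and scaling between arrays gave 1 between G88:5 and G88:9. In single-channel values with no replicate block, the G88 lines against the untransformed line gave 450, and no other call changed. The same values with the block, added after seeing the data, gave 302, so most of the move came with the single-channel values and not with the block. The 11 calls were made only with the array that had no scanner file of its own, since the series matrix values of the other 23 arrays gave 0. Whether its own values or the added precision of a complete loop brought features past the threshold was not tested. For the other changes the cause was not tested either. The 4 named features kept their direction under every alternative that gave them a value. They were picked by their smallest p in these same arrays, most of which the alternatives reuse, so this says little about stability. The dim-feature filters removed no feature, so they say nothing about stability. Leaving out a whole loop left a class test only, and camera and fry were not run because no features could be assigned to gene lists. Recorded backgrounds near 0 set no limit on dim features here.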

Other observations

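The settings in this part were chosen after the results were seen, except the count without G88:9 of replicate 1 and the series matrix values of all 24 arrays. The calls made in A78:3 under different settings overlapped. Of the 110 features called without the 3 arrays of low duplicate-spot agreement, 35 were higher and 75 lower in A78:3, and all 110 were among the 248 called without G88:9 of replicate 1. The 3 arrays are among the 4 left out for the 248, so these are nearly one setting. With 2 dye patterns removed and all arrays kept, 43 were called, of which 32 were among the 110 and 37 among the 248. These fits share most of their arrays, so the overlap is no independent evidence. In the left-out comparison of A78:3 with G88:9 of replicate 1, 78 of the 110 features and 163 of the 248 had the direction of the call.

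The arrays of the first slide lots had a larger spread of log2 ratios, with a median SD of 0.39, than those of the second, with 0.29. Swapping the dyes should turn the sign of a ratio, so that the r of the pair lies below 0. It ran from -0.379 for A78:3 over G88:9 to 0.583 for A78:5 over 95:88:22, both of replicate 2. In the 4 pairs with the untransformed line, all on the second lot, the r lay from 0.151 to 0.583. The remaining fitted pair on the second lot, A78:5 over G88:9 of replicate 2, had an r of -0.247. Of the 6 pairs on the first lots, 4 lay from -0.379 to -0.154. The other 2 were A78:3 over G88:9 of replicate 1 at -0.00834 and A78:3 over G88:5 of replicate 2 at 0.0794, where replicate 1 had -0.32.

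The repeated scanner file concerned the pairing of A78:4 with G88:5. The series matrix column of that array had a duplicate-spot r of 0.369. With the series matrix values of the 23 arrays fitted, A78:3 had 0 calls, where the 24 columns gave 11.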
